A study of Equus caballus with 6 samples.

How the data were processed

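The series holds 6 single-colour arrays of horse tissue, 1 for each of 6 regions. Per the labels' protocols, fetal hindlimbs and adult stifle cartilage were cut in frozen sections of 10 µm and stained with cresyl violet. Cells of each region were then collected by laser capture microdissection. Adult cartilage was 1500 to 2000 µm thick per the labels. RNA was amplified with SuperAmp, a PCR method that starts from cDNA of mRNA, which can alter the relative amounts of transcripts when little RNA is at hand. Per the labels, 250 ng of each cDNA was labelled with the dye Cy3 and hybridised for 17 h at 65 °C to Agilent horse arrays. The number of animals, and which animal gave which region, was not given in the sources used here.

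The authors deposited the scanner output of each array, made with Agilent Feature Extraction 10.7.3.1 per the file headers. Its processed signal is an intensity on a linear scale per the file headers, after background subtraction and spatial detrending, with spots at background replaced by small positive values. The files give flags, per the file headers, for spots well above background, saturated spots and outlier spots. The array in the files has 45220 spots, of which 1417 were controls and were left out. The other spots held 43603 probes. No spot was saturated. Between 3 and 80 outlier spots per array were left out, and spots of 1 probe were averaged. The deposited series table held the authors' values of the same arrays. Set against the scanner values it proved to be the processed signal divided by each array's median, on a linear scale, with a median of 1 in every column and a log2 correlation of at least 0.999998. It was used as an alternative.

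Groups were taken from the labels. Every group had 1 array, so no difference has a replicate check, and no p-value is given for the main values of the 8 comparisons. The limma fit, an alternative for stage, gives p-values over regions. The groups, comparisons, gene lists, alternatives and rule for named genes were set before the data were examined. The scaling was set then as the 75th percentile of all probes. Since under 50% of probes were well above background on each array, the main values instead took the 75th percentile over the 1765 probes well above background on all 6 arrays, which had been listed as an alternative. The 2 settings changed places after detection had been seen. Main values are log2 of the processed signal minus that percentile.

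Probes were named from the gene number, symbol or name in the files' probe descriptions, or from a RefSeq accession, through a table of horse genes of assembly TB-T2T, used for names only. Of the probes, 13534 were named by gene number, 9012 by symbol, 791 by a symbol missing from the table, 339 by gene name, 182 by an older symbol and 69 by accession. The other 19676 had no name. Symbols written with a hyphen were joined to their table form, a correction made after values had been seen. The 13706 genes include 698 whose symbol is only a locus number, which are not named here. For the 4614 genes with several probes, the reported probe was the one with the highest mean normalized value over the 6 arrays. A gene was called not above background only if none of its probes was above it.

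A gene entered a comparison of measured values when its reported probe was well above background on all arrays of the comparison. Genes at least 4-fold apart were counted in each direction. For a gene measured on every array of 1 side and on none of the other, a bound was computed: the bright side's mean against the dim side's mean of the higher of the lowest signal well above background and the probe's own signal. The error of a difference was taken from the spot errors that Feature Extraction gives, and from the spread between probes of a gene. Both leave out the variation between animals, dissections and amplifications. For stage, means over the 3 arrays of each age were compared, which treats regions as if they were replicates.

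For each comparison the named genes were the 8 with the largest difference per direction, or 10 for stage, ranked there by the gap between stages, among genes whose measured probes all went the same way. Added to these were up to 4 bounds per direction, 2 to 4 members with the largest difference of each gene list described, and a set of marker genes. The text names a selection of them, and some genes are not reported here. The 28 gene lists held 802 distinct members, of which 643 were on the array. A list's median was placed among those of 10000 random lists of equal size drawn from 10 bins of mean signal. Such percentiles describe these arrays and are not tests of the conditions. In all, 147 list medians had a percentile.

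The alternatives were other percentiles and sets of probes for scaling, quantile normalization, normexp correction of the mean spot signal with an offset of 50, the authors' values, the mean over probes, a wider and a narrower filter on dim genes, a 2-fold threshold, a requirement of 3 times the spot error, each array left out of the stage comparisons, and limma with regions as replicates. A count was taken to differ from the main one when it lay outside 1.5 times of it or its share of higher genes moved by over 10 percentage points.

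The code was tested on simulated data. For the intermediate interzone minus transient cartilage, over 4102 genes, 85 of 85 genes changed by 8-fold were counted at 4-fold, as were 5 of 115 changed by 3-fold and 0 unchanged genes. Of unchanged lists, 8% lay outside the central 95% of random lists. For superficial minus deep cartilage, over 1144 genes, the counts were 100 of 100, 3 of 100 and 0, with 5.5% of lists outside. The noise simulated for these counts was close to the median spot error. The pooled SD between probes of a gene was larger, 0.54 and 1.05 log2 units in these comparisons. Variation between dissections and amplifications was not simulated, so the counts of 0 do not show that the real counts hold no false genes. The limma fit of stage recovered 134 of 200 changed genes among 582, with 1 false call. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.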

Results

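Gene expression was measured in small regions of horse joint tissue collected by laser capture microdissection, a method that cuts chosen cells out of a thin section. 6 arrays were analysed, 1 per group. The 3 fetal regions came from hindlimbs at gestational day 40: the intermediate interzone and the outer interzone, layers of the tissue between the skeletal elements where the joint will form, and transient embryonic cartilage, the cartilage of the bone models that is later replaced by bone. The 3 adult regions came from articular cartilage at 15 years of age and were taken by depth from the surface: a superficial layer (outer 10%), a middle layer (20 to 30%) and a deep layer (50 to 90%). No group had a replicate, so differences below describe these 6 arrays and carry no p-value. The number of animals was not given in the sources used here. All 3 fetal arrays lay on slide 1 and all 3 adult arrays on slide 2.

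Signal over background differed widely between the arrays. Of 43603 probes, 16109 (36.9%) lay well above background in the intermediate interzone, 18874 (43.3%) in the outer interzone and 19445 (44.6%) in transient cartilage. In the adult the numbers were 11525 (26.4%) in the superficial layer, 3661 (8.40%) in the middle layer and 4729 (10.8%) in the deep layer. These probes named 5207, 5997 and 6279 genes on the fetal arrays and 3964, 1346 and 1709 on the superficial, middle and deep arrays. The housekeeping genes GAPDH, B2M and PGK1 were not well above background on the middle array. Signals were scaled between arrays on 1765 probes that were well above background on all 6. A gene was compared only where it lay well above background on every array of a comparison. Genes measured on 1 side only are given as bounds ("at least N-fold") against the lowest well-above-background signal of the dimmer array. Spots of one probe differed by a median SD of 0.08 to 0.18 log2 units, depending on the array. The number of arrays, not the spot error, limits the precision.

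**Figure D1:**
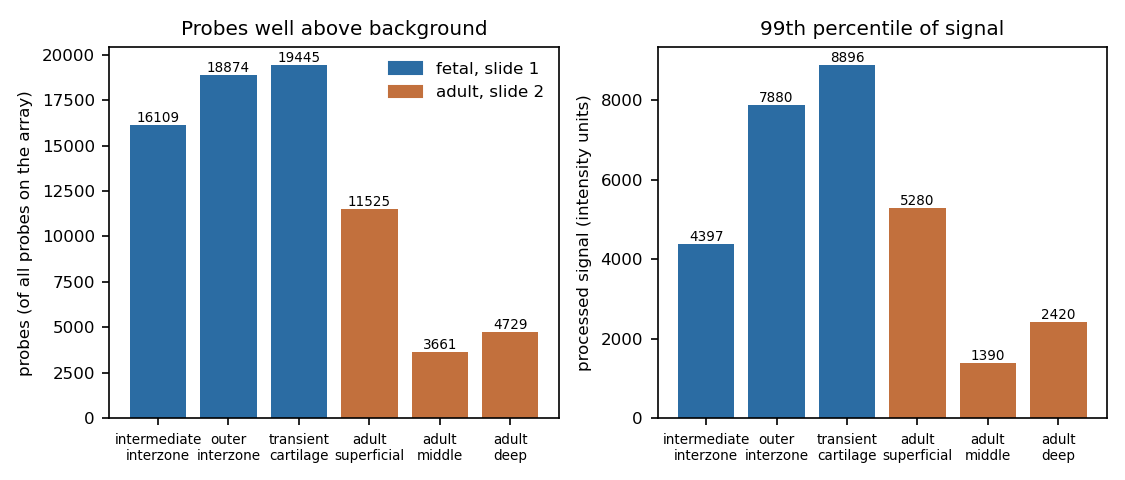
Number of probes well above background (left) and 99th percentile of the processed signal in intensity units (right) on each of the 6 arrays, with 1 bar per array. The middle and deep adult arrays have 3661 and 4729 probes above background, against 16109 to 19445 on the fetal arrays.

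The intermediate interzone was set against transient cartilage to ask how the future joint layer differs from cartilage that will become bone. PRG4, which encodes the joint lubricant lubricin, was 800.2-fold higher in the intermediate interzone. The secreted matrix protein gene EGFL6 was 417-fold higher, the homeobox gene BARX2 126-fold, the signalling ligand gene WNT11 82.8-fold and the growth factor gene PDGFC 81.6-fold. GDF5, a growth factor gene of joint formation, was not well above background in transient cartilage and was at least 135-fold higher in the intermediate interzone. In the other direction, MATN1 (matrilin 1) was 402-fold lower, ACAN (aggrecan) 130.5-fold, CYTL1 54.9-fold and LECT1 (chondromodulin) 35.9-fold. Other genes with large differences were CACNB3, 565-fold higher, EDIL3, 74.0-fold lower, and THBS1, 58.7-fold lower.

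Of 16 measured members of the list for cartilage matrix and chondrocytes, 14 were at least 2-fold lower in the intermediate interzone, 2 lay within 2-fold and 0 were higher. A further 8 members lay above background in transient cartilage only, as did 1857 genes in all, against 799 in the intermediate interzone only. The list median was -3.82 log2 units, below all 10000 random lists of equal size and signal level. COL2A1, the main cartilage collagen, was 21.8-fold lower, SOX9, the chondrocyte transcription factor, 10.1-fold lower and COMP 14.5-fold lower. Bounds included EPYC (epiphycan), at least 4666-fold lower, MATN3, at least 468-fold, COL11A2, at least 156-fold, and CHAD (chondroadherin), at least 105-fold. The cartilage differentiation genes IHH and RUNX2 lay above background in transient cartilage and in neither interzone layer, by at least 3.16-fold and at least 5.94-fold against the intermediate layer. COL10A1 and ALPL, genes of hypertrophy and mineralisation, lay above background on no array.

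Among joint interzone and joint-forming genes, 9 of 11 measured members were at least 2-fold higher in the intermediate interzone and 1 was lower. Their median was 2.65, above all random lists. They included OSR1 20.4-fold and OSR2 14.0-fold, transcription factor genes, and SFRP2 12.7-fold, a secreted WNT regulator. The hyaluronan receptor gene CD44 had a bound of at least 21.4-fold and FGF18 of at least 67.9-fold. The tendon, ligament and perichondrium list had a median of 2.74, with 7 of 8 measured members at least 2-fold higher, among them MKX 51.1-fold and THBS4 6.75-fold, and with ASPN (asporin) at least 439-fold higher. Of 16 measured fibrillar and non-cartilage collagen genes, 10 were at least 2-fold higher and 2 lower (median 2.00), for example COL6A3 27.9-fold and COL3A1 11.4-fold higher. In the BMP and TGF-beta list 13 of 18 were higher and 1 lower (median 2.07), with TGFB2 14.3-fold, ID3 15.0-fold and BMP4 at least 170.1-fold higher. Limb patterning transcription factors had a median of 1.75, with PRRX1 10.3-fold and MEIS2 7.99-fold higher, and EMX2 at least 165-fold higher. Cell cycle genes went the other way: 12 of 22 were at least 2-fold lower and 1 higher, and the median was -1.05, below all random lists. Over the scalings it ran from -1.41 to -0.045, and from -1.27 to -0.23 relative to the shift of all genes. Within the list, CCNB1 was 8.80-fold lower, RRM2 5.67-fold lower and MKI67 2.06-fold lower. All 38 ribosomal protein genes were measured, 14 of them at least 2-fold lower and 0 higher, with a median of -0.90. WNT pathway genes split, with 6 of 15 higher and 5 lower (percentile 54.5).

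In all, 651 of 4339 measured genes were at least 4-fold higher in the intermediate interzone and 291 at least 4-fold lower. The median over all genes was 0.36, the median spot error of a difference 0.21 and the median SD between probes of one gene 0.23 (pooled SD 0.54). After normexp background correction the counts were 330 and 40. Among markers of other tissues, skeletal muscle genes differed within the list: 4 of 7 measured were at least 2-fold higher and 0 lower (median 1.03, percentile 83.3), while DES, not above background in the intermediate interzone, was at least 12.8-fold lower. S100B, a gene of Schwann cells and of cartilage, was at least 50.6-fold lower and TAGLN (smooth muscle) at least 55.5-fold higher.

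The outer interzone was set against the same transient cartilage array, so both interzone comparisons share that array's error. PRG4 was 569-fold higher, EGFL6 183-fold, PDGFC 89.2-fold and the metalloproteinase inhibitor gene TIMP2 71.6-fold. EPYC was 279.6-fold lower, MATN4 78.0-fold, MATN3 76.9-fold, MATN1 76.4-fold and the homeobox gene DLX5 77.2-fold. GDF5 was at least 48.5-fold higher, CD44 at least 52.0-fold and the matricellular gene SPARCL1 at least 269-fold. Of 21 measured cartilage matrix genes 18 were at least 2-fold lower and 1 higher (median -3.27), with COL2A1 13.3-fold lower and ACAN 29.1-fold lower. Of 12 joint interzone genes 10 were higher and 1 lower (median 2.41). The tendon, ligament and perichondrium median was 3.28, with THBS4 22.1-fold higher. These 3 medians lay beyond all random lists. Ribosomal protein genes had a median of -0.83, with 13 of 38 at least 2-fold lower and 0 higher. The BMP and TGF-beta median was 0.39 (percentile 79.3) and the cell cycle median -0.17 (percentile 11.8), and both took either sign over the scalings (-0.02 to 0.77 and -0.40 to 0.21). The epithelial genes KRT17 and EPCAM were at least 113-fold and at least 10.5-fold higher in the outer interzone. In all, 513 of 4831 genes were at least 4-fold higher and 403 lower. The split followed the scaling: it was 690 and 288 with the 50th percentile, and 157 and 179 after normexp correction.

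**Figure D2:**
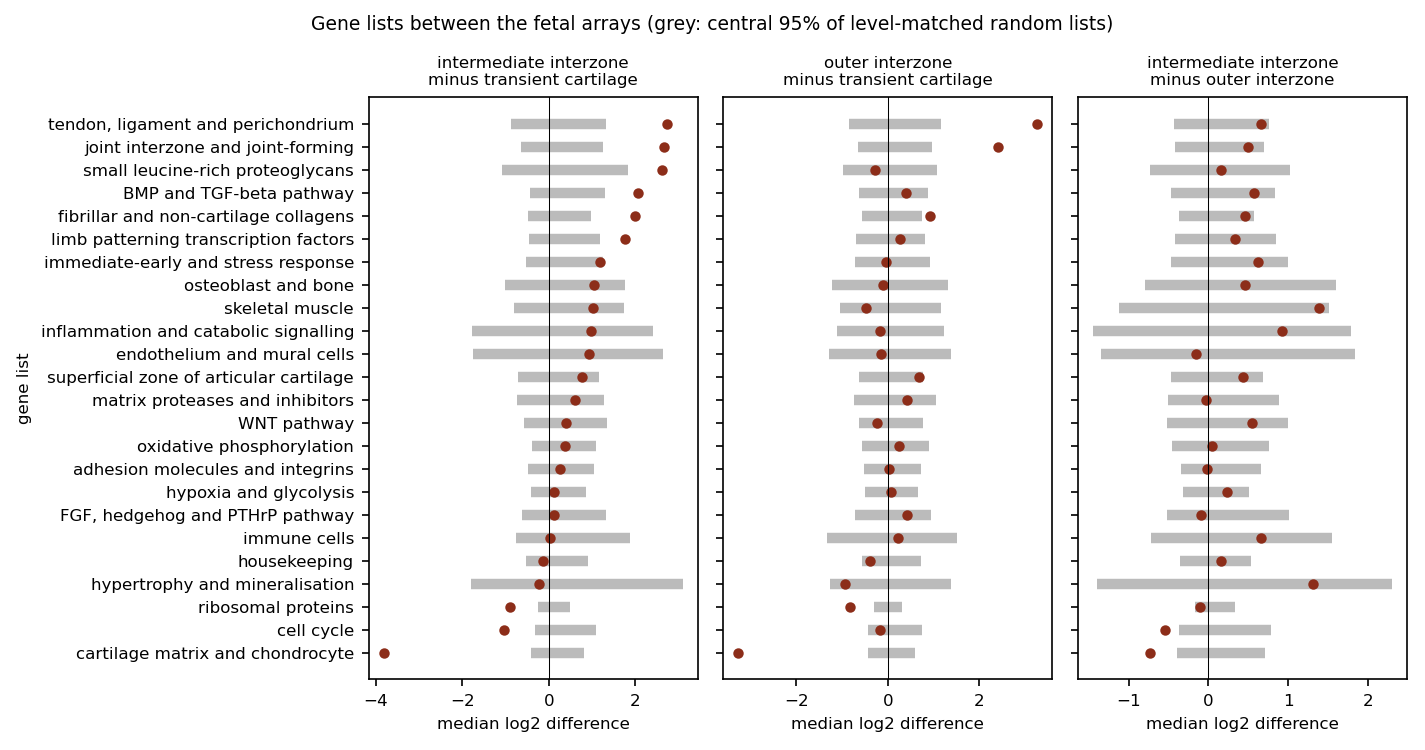
Median log2 difference of each gene list (red points, horizontal axis) between the fetal arrays, 1 panel per comparison, with the central 95% of level-matched random lists in grey. The cartilage matrix list lies lowest in all 3 panels, with medians of -3.82, -3.27 and -0.73, and the joint interzone list at 2.65, 2.41 and 0.49.

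The intermediate and outer interzone layers were compared with each other to see how the parts of the interzone differ. CALB2 (calretinin) was 93.8-fold higher in the intermediate layer, the oxygen sensor gene EGLN2 82.7-fold, the cadherin gene CDH10 76.1-fold and the ubiquitin ligase gene PJA1 112-fold. CYTL1 was 50.4-fold lower in the intermediate layer. GDF5 was 2.78-fold higher, DCN (decorin) 11.5-fold, FGF10 34.1-fold and FGF18 7.95-fold. The bound for SEMA3B was at least 195-fold higher. PRG4 and COL1A1 were 1.41-fold and 1.38-fold higher. Cartilage matrix genes had a median of -0.73 (percentile 0.11), with 6 of 16 at least 2-fold lower in the intermediate layer and 2 higher. ACAN was 4.48-fold lower, SOX9 3.55-fold and MATN1 5.26-fold. With normexp correction, and relative to the shift of all genes, the MATN1 difference was 0.0042 log2 units. Cell cycle genes had a median of -0.54 (percentile 0.54), with 9 of 21 lower and 3 higher, among them RRM2 4.56-fold and MKI67 3.48-fold lower. The joint interzone list had a median of 0.49 (percentile 89.9). Muscle genes MYL1 and TPM2 were 25.7-fold and 5.07-fold higher in the intermediate layer, and KRT17 and EPCAM at least 58.4-fold and at least 5.40-fold lower. The probes for HBB (a blood haemoglobin) disagreed: the reported probe was 13.5-fold higher, and the mean over its probes gave -0.92 log2 units.

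Between these layers 470 of 4311 genes were at least 4-fold higher in the intermediate interzone and 312 lower. The split was 377 and 381 with the 50th percentile and 351 and 16 after normexp correction, so which layer had more high genes was not settled. The median spot error of a difference was 0.21 and the pooled SD between probes of one gene 0.55. Of 224 genes with several probes at least 4-fold apart by the probe mean, 219 had all probes on the same side of 0.

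**Figure D3:**
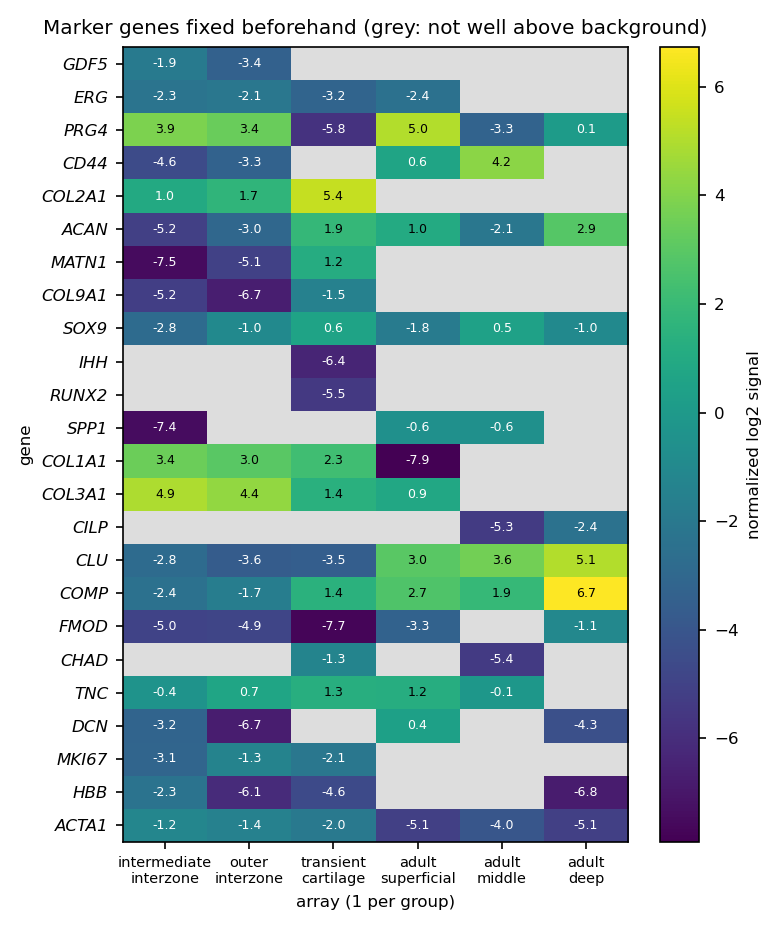
Normalized log2 signal of the marker genes fixed beforehand (vertical axis) on each of the 6 arrays (horizontal axis), 1 array per group. Grey cells were not well above background. PRG4 stands at 3.86 in the intermediate interzone and 5.02 in the superficial layer, against -5.78 in transient cartilage.

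The adult layers were compared to ask how expression differs with depth in articular cartilage. PRG4 followed depth unevenly: it was 313-fold higher in the superficial than in the middle layer and 30.0-fold higher than in the deep layer. Against the deep layer, the matricellular gene THBS1 was 165-fold higher in the superficial layer, DCN 27-fold, the hyaluronan receptor gene CD44 at least 182-fold, TNC (tenascin C) at least 271-fold, COL3A1 at least 212-fold and the adhesion gene VCAM1 at least 236-fold. The antimicrobial peptide gene DEFB4B had the largest bound among the genes higher in the superficial layer, at least 1015-fold. Detection was lower on the deep array: 2628 genes lay above background on the superficial but not the deep array, against 397 the other way. For genes given by a bound as higher in the superficial layer, a depth difference was not separated from that lower detection. For measured folds, a depth difference was not separated from uneven amplification of transcripts. COMP was 16.3-fold lower in the superficial layer, CYTL1 48.5-fold, the stress-responsive cell cycle inhibitor gene CDKN1A 293-fold and CILP (cartilage intermediate layer protein) at least 60.3-fold. VIT, a matrix protein gene, was at least 3232-fold lower. Of 8 cartilage matrix genes measured in both, 5 were at least 2-fold lower and 1 higher (median -1.99, percentile 7.0). Of 7 inflammation and catabolic signalling genes, 4 were at least 2-fold higher and 2 lower, with a median of 1.78 against -0.82 for all genes (percentile 99.04). They included LCN2 4.71-fold and SOD2 5.50-fold, and C1R at least 420.4-fold and CCL20 at least 376-fold by bounds. Of 9 adhesion and integrin genes 5 were higher and 1 lower, with a median of 1.14 (percentile 99.7, and 0.22 to 2.22 over the scalings). JUN and FOS, immediate-early genes, were 31.5-fold and 5.88-fold lower in the superficial layer.

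Against the middle layer, the superficial layer had higher PROCR, the protein C receptor gene, by 88.4-fold, LCN2 (lipocalin 2) by 81.7-fold and the interleukin gene IL6 by 14.4-fold. The heparan sulfate proteoglycan gene SDC4 was at least 418-fold higher, COL3A1 at least 117-fold and DCN at least 86.8-fold. For these bounds a depth difference was not separated from the lower detection on the middle array. COL16A1 was 592-fold lower in the superficial layer, the mitochondrial enzyme gene ECH1 577-fold, the proteasome gene PSMD3 627-fold and the cytokine gene CSF3 281-fold. In the adult layer pairs, a depth difference was not separated from uneven amplification of transcripts for measured folds either. Of genes measured in the superficial and middle layers, 46.6% were at least 4-fold apart, against 18.1% to 21.7% between fetal arrays. The hyaluronan synthase gene HAS2 was 84.2-fold lower and CD44 11.4-fold lower. The list for the superficial zone had a median of 1.20 against -1.50 for all genes (percentile 99.3) over 6 measured members. For superficial minus deep its median was 0.36 (percentile 93.1), with 2 of 6 at least 2-fold higher and 2 lower, and it took either sign over the scalings (-0.56 to 1.44). The 4 immune cell markers measured in both layers were lower in the superficial layer, by a list median of -3.91 (percentile 0.94, and -4.90 to -1.97 over the scalings), with CSF1R 22.4-fold and the chemokine gene CCL3 42.0-fold lower. DRB and LAPTM5 lay above background in the superficial and deep layers but not in the middle layer.

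Between the middle and deep layers, ACAN was 32.0-fold lower in the middle layer, COMP 29.0-fold, COL11A1 46.9-fold and CILP 7.81-fold. CYTL1 was at least 463-fold lower, TIMP2 at least 699.9-fold and FMOD (fibromodulin) at least 30.2-fold. Detection was low on both arrays, so for genes given by a bound in this pair a depth difference was not separated from lost detection. CD44 was at least 2084-fold higher in the middle layer, THBS1 187-fold, CSF3 at least 2150-fold, and the collagenase gene MMP1 at least 197-fold and stromelysin gene MMP3 at least 423-fold. Of 6 cartilage matrix genes 4 were at least 2-fold lower in the middle layer and 2 higher (median -4.48, percentile 0.13). Of 6 superficial zone genes 5 were lower and 0 higher (median -2.70, percentile 0.12, and -3.56 to -1.33 over the scalings). Of 5 measured hypoxia and glycolysis genes 1 was at least 2-fold higher and 1 lower (median 0.73, percentile 53.2). GAPDH and LDHA, glycolytic genes, were not above background on the middle array and were at least 84.6-fold and at least 69.1-fold lower, but 25 of 58 ubiquitous genes measured in the superficial layer (43.1%) were missing on that array, so these bounds do not show a depth difference in glycolysis.

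The numbers of genes at least 4-fold higher and lower were 98 and 370 of 1005 for superficial minus middle, 139 and 262 of 1264 for superficial minus deep, and 104 and 64 of 817 for middle minus deep. With the 50th percentile they were 242 and 74, 230 and 120, and 45 and 98, so the side with more high genes turned with the scaling in all 3 pairs. That setting moved every difference, bounds included, by 1.95, 1.09 and -0.86 log2 units. A further 2888 genes lay above background on the superficial but not the middle array, against 295 the other way. The median spot errors of a difference were 0.24, 0.22 and 0.25. The pooled SD between probes of one gene was larger, at 0.96, 1.05 and 0.86 log2 units.

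Fetal and adult differences were set against each other to ask whether genes that separate interzone from transient cartilage also separate superficial from deep adult cartilage. Across genes, which are not independent replicates, Pearson's r between the intermediate interzone minus transient cartilage and superficial minus deep differences was 0.014 over 982 genes (Spearman's rho -0.015). It was -0.019 over 1046 genes for the outer interzone minus transient cartilage (rho -0.026) and 0.059 over 985 genes for the intermediate minus outer interzone (rho 0.012). In the first of these, 8 genes were at least 4-fold higher in both, against 9.37 for independent lists, and 13 were lower in both, against 8.74. PRG4 was among the former, and COMP and CYTL1 among the latter. Genes given only by a bound in either comparison did not enter, so these values say nothing of them.

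Adult and fetal regions were compared over the means of the 3 arrays of each stage. ANGPTL7, an angiopoietin-like gene, was 509.9-fold higher in the adult, CLU (clusterin) 148-fold, PCOLCE2, a procollagen processing enhancer gene, 381-fold, TIMP3 160.0-fold and the membrane protein gene TM4SF1 132-fold, each of them on every adult array above every fetal array. Of the inflammation list, 4 genes could be compared: SAA1 (serum amyloid A), at least 34851-fold higher, and NOS2, the inducible nitric oxide synthase gene, at least 658-fold, lay above background on all 3 adult arrays and on no fetal array. LCN2 and PTGS2 lay above it on all 6 arrays and were 3.95-fold and 1.19-fold higher. H19, an imprinted fetal RNA, was 65.9-fold lower in the adult, the glycolytic enzyme gene ALDOC 32.2-fold, the microfibril gene MFAP2 23.2-fold and ACTA1 9.29-fold. Detection was lower on the adult arrays: 1321 genes lay above background on all fetal arrays and on no adult array, against 33 the other way. COL2A1, COL9A2 and COL9A3 were among the 1321 and were at least 857-fold, at least 1716-fold and at least 742-fold lower. Not all cartilage genes were lower: COMP stood at 1.88 to 6.73 log2 units on the adult arrays, against -2.44 to 1.42 on the fetal arrays. The median of the measured cartilage matrix genes ran from -0.21 to 3.04 over the scalings, and from -1.20 to 0.33 relative to the shift of all genes.

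Of 5 adhesion and integrin genes measured on all 6 arrays, all 5 were at least 2-fold higher in the adult (median 3.59, percentile 99.7). Members not above background on the middle or deep array could not enter, here or in the superficial zone list below. TNC, a member of both lists, lay above background on all fetal arrays but not on the deep array and was left out. Over the scalings this median ran from 3.04 to 6.29, and from 2.37 to 3.59 relative to the shift of all genes. Among the 5 were FN1 (fibronectin) 25-fold, THBS1 35.3-fold and THBS2 12-fold higher. THBS1 was lower on the deep array (-4.34) than in transient cartilage (-1.38). The superficial zone list had a median of 2.47 over 5 members (percentile 98.9). Over the scalings it ran from 1.93 to 5.17, and from 0.89 to 2.47 relative to the shift of all genes. Of the 1321 genes found on the fetal arrays alone, 15 were in the cell cycle list, 14 of them with a bound of at least 2-fold, such as CCNB2 at least 44.1-fold, MKI67 at least 29.1-fold and RRM1 at least 32.7-fold lower. Limb patterning genes HOXA10 and HOXC9 were at least 128-fold and at least 47.5-fold lower, and SFRP2 at least 507-fold lower. The oxidative phosphorylation genes SDHB and COX5A were also among the 1321, by at least 34.4-fold and at least 37.1-fold. For such genes a difference between the stages was not separated from the lower detection on the adult arrays.

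By the stage means, 88 of 582 genes were at least 4-fold higher in the adult and 55 lower; every adult array was at least 4-fold above every fetal array for 16 genes and at least 4-fold below for 11. The split was 451 and 2 when arrays were scaled on all probes, 360 and 20 with quantile normalization and 63 and 73 with the 50th percentile. It was 143 and 95 without the middle array, and 322 and 379 of 2371 genes without the middle and deep arrays, a setting chosen after the data were seen. Each stage lay on 1 slide of its own, so stage and slide cannot be told apart.

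Adult cartilage was also set against transient cartilage alone, cartilage against cartilage. TM4SF1 was 580.0-fold higher in the adult, ANGPTL7 490.2-fold, CLU 172-fold, PRG4 84.6-fold and the tendon transcription factor gene MKX 70.9-fold. PRG4 varied with the layer, at 5.02, -3.27 and 0.11 log2 units on the superficial, middle and deep arrays against -5.78 in transient cartilage. SAA1 was at least 43904-fold higher and CFB, a complement gene, at least 2792-fold. H19 was 84.4-fold lower and COL11A1 43.3-fold, with -5.83 on the middle array and -0.81 and -0.28 on the others. COL2A1 was at least 5683-fold lower, EPYC at least 2382-fold and MATN1 at least 295-fold. The cartilage matrix median was -1.63 (percentile 0.73), with 5 of 6 measured genes at least 2-fold lower and 12 more above background in transient cartilage but on no adult array, as were 2838 genes in all, against 75 the other way. Over the scalings this median ran from -2.01 to 0.96, and from -3.75 to -1.63 relative to the shift of all genes. COMP went the other way, 5.11-fold higher, mostly through the deep array: it stood at 2.71, 1.88 and 6.73 on the superficial, middle and deep arrays against 1.42 in transient cartilage. With quantile normalization, relative to the shift of all genes, its difference was -0.17 log2 units. The superficial zone median was 6.06 (percentile 99.9) over 5 genes, 4 of them higher. List members not above background on the middle or deep array did not enter. Of 24 ribosomal protein genes 14 were at least 2-fold lower and 0 higher (median -1.04, percentile 0.03), with a median of up to 1.56 when arrays were scaled on all probes. Of the 2838 genes above background in transient cartilage but on no adult array, 26 were cell cycle genes, 21 of them with a bound of at least 2-fold. In all, 147 of 656 genes were at least 4-fold higher and 60 lower. The counts were 495 and 3 with scaling on all probes, 222 and 105 without the middle array, and 645 and 424 of 3047 without the middle and deep arrays. Scaling on the 75th percentile of all probes moved every difference of this comparison, bounds included, by 2.59 log2 units.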

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

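The tests of explanations in this part were chosen after the results they bear on had been seen, except the test of second probes, whose outcomes were set down before its value was known. Probes without a gene name entered no comparison, and many carried signal. Of them, 899 were well above background on all 6 arrays, 2001 on all 3 fetal arrays and no adult array, and 40 on all 3 adult arrays and no fetal array.

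Genes that nearly every cell uses were missing on the dim adult arrays: of 58 ribosomal protein, oxidative phosphorylation and housekeeping genes measured in the superficial layer, 25 (43.1%) were not above background in the middle layer and 20 (34.5%) in the deep layer, against 0 to 2.90% between fetal arrays. A uniformly dimmed superficial array would have kept 1742 genes, of which 1320 (75.8%) were missing on the middle array (at least 61.7% under every scaling tried). Of 50 ubiquitous genes among the 1742, 20 (40.0%) were missing. Between fetal arrays the same count of all genes gave 13.6% to 18.6%. Genes truly lower in the middle layer also count as missing. The main scaling rests on probes that stayed above background on the middle array, so a stronger dimming was not tested. The tables thus argue against a lower brightness of the whole array only at the size that the scalings give. They also argue against errors of single spots or probes, at least for the 37 genes of these lists with 2 or more probes well above background in the superficial layer: the second probe was missing on the middle array in 16 of 20 genes (80.0%) where the brightest was missing and in 2 of 17 (11.8%) where it was not, percentile 100 among permutations of the second probes. Uneven loss of transcripts while little RNA was amplified may account for the missing genes and stays open: their lost share lay at percentile 0 among gene lists matched on the superficial signal (median 67.2%), but such lists also hold genes that could truly be lower in the middle layer, which is why a low percentile was, after it had been seen, no longer taken to exclude this explanation. A real difference between the layers was not tested and stays open as well.

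SAA1, at least 34851-fold higher in the adult, and NOS2, at least 658-fold higher, lay above background on all adult arrays and no fetal array. Against immune cells in the adult tissue alone, 2 to 4 of 19 immune cell markers stood 4-fold or more above the lowest well-above-background signal on the fetal arrays and 2 to 3 on the adult arrays. AIF1 did so on all fetal arrays (9.89 to 50.4 times that signal) and was above background on no adult array. CD68 stood at 13.6 to 60.6 times on the fetal arrays against 0.20 to 3.05 on the adult arrays, the highest in the middle layer. Each value is a multiple of that array's own lowest well-above-background signal. On the middle array that signal was 7.87 where the percentile used for scaling was 507, against 9.24 and 2400 in the intermediate interzone. The CD68 multiple of 3.05 therefore does not show a lower scaled value in the middle layer than on the fetal arrays. Low values on the middle and deep arrays decide little, since 43.1% and 34.5% of the ubiquitous genes were missing there too. On the superficial array AIF1 stood at 0.22 times and CD68 at 2.21 times that signal. Immune cells may still have contributed, since the share on the superficial array, 10.5%, decides nothing against bounds that were set after it had been seen, and CSF1R (11.3 times), CCL3 (35.6 times) and DQA (5.93 times) on the middle array and DRB (25.6 times) on the deep array stood higher than on any fetal array. Slide and stage cannot be told apart, since 0 slides held arrays of both stages, and a difference between fetal and adult tissue, not tested apart from the slide, stays open.

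Ribosomal protein genes were lower in both interzone layers than in transient cartilage. The tables argue against a scaling that depends on signal as the cause: the list median minus that of level-matched random lists was -0.92 and -0.75 with quantile normalization and -0.96 and -0.81 with normexp correction, in the intermediate and outer layers. A constant factor per array moves all genes alike and so was not tested by this, but the list median lay below 0 under all 6 scalings, from -1.07 to -0.45. Both comparisons rest on the same transient cartilage array, so an error of that array stays open, as do a loss of transcripts during amplification and a difference between the tissues, none of which was tested.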

How the results depend on the processing

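The run without the middle and deep arrays together, and the regrouping of arrays in the limma fit, were chosen after seeing the data; the other alternatives were planned. Signal over background limited the adult comparisons, with 3661 probes above it on the middle array and 4729 on the deep array. No paired analysis was possible because each group compared had 1 array, so the groups share fewer than 2 replicate numbers. Counts below are genes at least 4-fold apart, higher and lower in brackets, and the cause of a difference from the main count was not tested except where the setting itself gives it.

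With the 50th percentile of all probes the count was 758 (377/381) for intermediate minus outer interzone, 978 (690/288) for outer interzone minus transient cartilage, 316 (242/74) for superficial minus middle, 350 (230/120) for superficial minus deep, 143 (45/98) for middle minus deep, 136 (63/73) for adult minus fetal and 180 (59.4% of them higher) for adult minus transient cartilage. The authors' values, scaled on the median, gave these counts too, apart from 760 (373/387) for intermediate minus outer interzone. With the 75th percentile of all probes, the setting first planned as the main one, superficial minus deep gave 620 (88/532), middle minus deep 137 (48/89), adult minus fetal 453 (451/2) and adult minus transient cartilage 498 (495/3). Quantile normalization gave 773 (41/732) for superficial minus middle, 797 (57/740) for superficial minus deep, 380 (360/20) for adult minus fetal and 448 (424/24) for adult minus transient cartilage. These scalings moved the median of all genes by between -1.61 and 2.705 log2 units in the adult and stage comparisons and by -0.26 to 0.38 between fetal arrays.

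Counts for all 8 comparisons follow in the order intermediate minus outer interzone, intermediate interzone and then outer interzone minus transient cartilage, superficial minus middle, superficial minus deep, middle minus deep, adult minus fetal and adult minus transient cartilage. Normexp correction gave 367 (351/16), 370 (330/40), 336 (157/179), 437 (46/391), 258 (71/187), 88 (41/47), 77 (56/21) and 115 (90/25). It moved the median of all genes by -0.34 to 0.58. Counting genes above background on at least 1 array, with dim values at the floor, gave 2079 (1098/981), 2303 (1267/1036), 2378 (1189/1189), 2178 (1434/744), 2129 (1598/531), 832 (335/497), 2610 (949/1661) and 3432 (1481/1951), since more genes enter. A 2-fold threshold gave 1865 (1104/761), 2186 (1412/774), 2178 (1207/971), 767 (162/605), 787 (221/566), 431 (325/106), 327 (228/99) and 423 (308/115). The mean over probes gave 177 (90/87) for adult minus fetal and 241 (144/97) for adult minus transient cartilage. The brighter genes only, and the requirement of 3 times the spot error, moved no count past the limits set.

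Leaving out 1 array at a time gave 147 to 238 genes for adult minus fetal and 292 to 327 for adult minus transient cartilage, the highest each time without the middle array (143/95 and 222/105). Without the middle and deep arrays the counts were 701 (322/379) of 2371 genes and 1069 (645/424) of 3047. With limma, regions standing in for replicates, 42 genes (26/16) of 582 passed an adjusted p of 0.05 and 4-fold; p-values over regions are too small where regions share an animal. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many as the real 42, and the highest other gave 0. 10 splits are too few for a share under 0.05.

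The correlation between the intermediate minus outer interzone and superficial minus deep differences was -0.038 with normexp correction, and 23 of 24 correlations under alternatives stayed close to the main value. A constant factor per array cannot change Pearson's r, so the values under such scalings, the authors' values included, were fixed in advance. The narrower filter on dim genes kept the same genes and so gave the same values. Only quantile normalization, normexp correction, the mean over probes and the wider filter could move a correlation. Relative to the shift of all genes, 4 values of named genes at least 4-fold apart took the other sign: MATN1 in intermediate minus outer interzone with normexp correction (0.0042), HBB with the mean over probes in intermediate minus outer interzone (-0.92) and intermediate interzone minus transient cartilage (-2.40), and COMP in adult minus transient cartilage with quantile normalization (-0.17). Of 1672 values of named genes, 1259 stayed close to the main value, and 13, these 4 included, took the other sign. Relative to the shift, the values under a constant factor per array could not move. Of 1176 list medians 1041 stayed close and 135 moved, and here too the values under a constant factor per array were fixed in advance. After the shift 77 took the other sign, none of them of a list beyond the central 95% of random lists. With the shift left in, some of those lists did so when arrays were scaled on the 75th percentile of all probes. These were 1 of 3 such lists for adult minus fetal and 2 of 4 for adult minus transient cartilage.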

Other observations

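Some results of gene lists fixed beforehand were not described above, and they were picked here after their values had been seen. Small leucine-rich proteoglycans, which bind collagen fibrils, differed within the list between the intermediate interzone and transient cartilage. OGN was 30.1-fold higher in the intermediate interzone, PODN 24.5-fold and BGN (biglycan) 5.69-fold, while PRELP was 3.23-fold lower and LUM (lumican) 2.58-fold lower. The list median was 2.62 (percentile 99.8) over 6 measured genes, 4 of them at least 2-fold higher and 2 lower. Immediate-early and stress genes had a median of 1.18 (percentile 96.8) in the same comparison, with 9 of 13 at least 2-fold higher and 2 lower: FOS was 9.16-fold higher and JUN 6.29-fold, while MYC was 13.7-fold lower. Between adult and transient cartilage, the hypoxia and glycolysis list had a median of -2.66 (percentile 0.76), with 3 of 5 genes at least 2-fold lower and 0 higher, among them P4HA2 7.06-fold and BNIP3L 6.34-fold lower. BNIP3L was not lower on the superficial array (-1.41 against -1.64). Over the scalings this median ran from -3.04 to -0.072, and from -2.92 to -1.17 relative to the shift of all genes.

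In the middle adult layer, adhesion genes were higher than in the deep layer by a median of 2.42 (percentile 99.7) over 5 genes, with THBS1 187-fold and SDC2 14.7-fold higher but FN1 5.93-fold lower. The 3 immune cell markers measured in both layers were all at least 2-fold higher in the middle layer, CSF1R by 15.2-fold, CCL3 by 12.4-fold and DQA by 7.60-fold, and DRB went the other way, at least 14.2-fold lower.

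Some genes went opposite ways in the fetal and adult comparisons, by counts without a test. Of 982 genes measured in both, 25 were at least 4-fold higher in the intermediate interzone than in transient cartilage and at least 4-fold lower in the superficial than in the deep adult layer, against 17.1 for independent lists. FMOD, FOS, JUN and TIMP2 were among them. THBS1 was among 4 genes that went the reverse way, against 4.79. The counts of genes that went the same way, 8 and 13, also lay on either side of their values for independent lists, 9.37 and 8.74.

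Over the 582 genes measured on all 6 arrays, Pearson's r between fetal arrays was 0.88 to 0.92, and between adult arrays 0.72 to 0.81. Between a fetal and an adult array it was 0.59 to 0.76. The arrays did not group by stage alone: the superficial array stood at 0.75 to 0.76 with the fetal arrays, against 0.72 with the middle and 0.81 with the deep array. The lower fetal to adult values came from the middle (0.59 to 0.62) and deep (0.66 to 0.69) arrays. These are correlations across genes, which are not independent replicates.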
